A study of Mus musculus with 37 samples.

How the data were processed

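Amplicons of the V3–V4 region of bacterial 16S rRNA genes were sequenced from stool DNA of adolescent mice of both sexes, born to dams that drank 10% ethanol early in pregnancy (prenatal alcohol exposure, PAE) or water throughout (control). Per the labels, sequencing was paired-end with 2 × 250 cycles on an Illumina NovaSeq. The submitters' processing notes name cutadapt, Bowtie2 and the mouse build GRCm39 without their roles or versions. The denoiser, the classifier and the reference taxonomy are not given in the sources used here. The deposited table holds raw counts, whole-number reads per sequence variant and library with no normalization. Its 6100 rows, each treated as 1 amplicon sequence variant (ASV), cover 37 libraries. A separate deposited table gives taxon names from kingdom to species for 6098 of the rows. The short-chain fatty acid and blood measurements of the study were not analysed here.

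Libraries were assigned to the groups named in their labels: control male (n = 11), PAE male (n = 10), control female (n = 7) and PAE female (n = 9). Replicate numbers in the text are the numbers in the library labels. In 2 control male libraries the title and the description exchange names, which leaves their group unchanged. Dam, litter, cage and batch are not given in the sources used here, so each library was treated as an independent sample. Rows without taxonomy (2 rows, 22 reads), rows unassigned or assigned to Eukaryota (2 and 1 rows, 10 reads) and rows assigned to chloroplasts or mitochondria (10 rows, 1490 reads) were left out, which kept 6085 rows and 99.99% of 16140229 reads. Counts were summed per phylum, family and genus. Rows without a genus name (7.96% of reads) were summed under their lowest named rank and called unclassified of that rank.

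Taxa with at least 5 reads in at least 7 libraries were tested with edgeR 4.0.16 (R 4.3.3), with TMM scaling and a quasi-likelihood F-test on a design of 4 group means: 111 of 431 genera, 553 ASVs, 60 families and 15 phyla. Contrasts were PAE against control within each sex, the difference of these contrasts between sexes (interaction), and male against female within controls and within PAE. Benjamini-Hochberg adjusted p under 0.05 was the threshold for a call. Fold changes of shares are ratios of group means of the percent of reads. Where 1 group had no read, the fold is a lower bound against 3 reads over that group. Where a group had 1 to 3 reads, the mean share of the other group was divided by the pooled share of that group, and the ratio is given with its 95% counting interval. Such intervals and bounds cover counting error only. All p-values measure the spread between libraries.

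Community measures used ASV counts rarefied to 102655 reads: Bray-Curtis distances with a permutational multivariate analysis of variance, which gives the percent of variation between groups (R2), distance to the group centroid, the Shannon index (natural logarithm) and observed ASVs. The log2 ratio of Firmicutes to Bacteroidota used all reads kept. Differences between groups were tested with two-sided permutation tests, exact over all splits where a group had fewer than 10 libraries and with 100000 permutations otherwise. Interactions were tested by permuting residuals of the additive model, 9999 times for R2 and 100000 times otherwise. Shares of 16 taxon lists were tested as summed percents of reads, with Benjamini-Hochberg adjustment over the lists: butyrate producers, propionate and succinate producers, Muribaculaceae, Lachnospiraceae, Oscillospirales families, Erysipelotrichales families, lactic acid bacteria, bifidobacteria, mucus-associated bacteria, sulfate and sulfite reducers, Enterobacterales, segmented filamentous bacteria, Rikenellaceae, Prevotellaceae, reagent and skin contaminants, and plastid and mitochondrial reads. List members came from textbook knowledge.

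The groups, main tests, lists, alternatives and the rule for named taxa were fixed before the data were examined. The interactions of the log2 ratio of Firmicutes to Bacteroidota and of the list shares were not among the tests so fixed. Neither were male against female for phyla, families, ASVs, composition, the Shannon index and observed ASVs. The rule names, for PAE against control in each sex, phyla with a mean share of at least 0.5%, the 10 genera with the highest mean share, the 8 called genera per direction with the smallest adjusted p, up to 3 members per list with the smallest p, and up to 3 ASVs per direction. It names 6 genera for the interaction and up to 4 per direction for male against female. Alternatives were TMMwsp scaling, library totals, DESeq2 1.42.0, limma 3.58.1 on centred log-ratios of counts plus 0.5, looser and stricter filters (10 reads in 18 libraries), all rows, depth as a covariate, the libraries of 1 sex alone, controls numbered 1 to 10 or 30 to 37 alone, and leaving out each library. Added after seeing the data were PAE libraries numbered 11 to 19 or 20 to 29 alone, leaving out 9 libraries that stand apart (replicates 3, 10, 20 to 24, 27 and 28), and a limma fit with a random block for 4 runs of label numbers. The runs were 1 to 10, 11 to 19, 20 to 29 and 30 to 37, the first and last of controls and the others of PAE. The 9 libraries were picked from these data, and PAE libraries 20 to 24, 27 and 28 hold the highest Bacteroides shares. Weaker calls of such genera without them are therefore partly built in. The call rate of the edgeR fit was tested on simulated data with male group sizes. A set of genera and a set of ASVs were drawn, each mixing 4-fold and 16-fold changes. Of 30 changed genera among 111, 26.7% of those changed 4-fold and 46.7% of those changed 16-fold were recovered, with 0 unchanged genera called. Of 200 changed ASVs among 553, 0% of those changed 4-fold and 13% of those changed 16-fold were recovered. Over both sizes together, 5 unchanged ASVs were called. Such false calls were a larger part of the simulated ASV calls than the threshold for a call allows. The ASV calls in males, from the same fit, may therefore include more false ones than that threshold implies. Further computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.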

Results

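The stool microbiota of 37 adolescent C57Bl/6 mice was profiled from 16S rRNA gene amplicons, to ask whether exposure to alcohol in the womb changed it and whether the sexes differed. Libraries came from 11 control males, 10 PAE males, 7 control females and 9 PAE females. Totals ranged from 102672 to 1813237 reads per library, with a median of 293111. They spanned 196668 to 781609 reads in control males, 102672 to 740925 in PAE males, 177506 to 1813237 in control females and 152720 to 1255425 in PAE females. On the log2 scale total reads differed between PAE and control by -0.55 in males (permutation p = 0.130) and by 0.23 in females (exact permutation p = 0.682). In control males Bacteroidota held 51.6% ± 7.0 and Firmicutes 41.6% ± 4.97 (SD, n = 11).

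In males, Bacteroides, a genus of anaerobic polysaccharide degraders, rose from 3.06% ± 1.71 of reads in controls (n = 11) to 17.3% ± 13.3 in PAE (SD, n = 10), with a log2 fold change of 3.30 (SE 0.67, edgeR adjusted p = 0.000650). The mean share was 5.67-fold higher in PAE. The family Bacteroidaceae, with the same mean shares, had a log2 fold change of 2.64 (SE 0.52), so its size varies with the rank fitted. Blautia, a genus of acetate-forming Lachnospiraceae, rose from 0.272% ± 0.264 to 6.66% ± 6.86 (log2 fold change 5.48, SE 1.19, edgeR adjusted p = 0.00104). Bacteroides was above the control median in 10 of 10 PAE males and Blautia in 9 of 10, and 5 of 10 exceeded every control for either genus. Those 5 were PAE males 20 to 24, where Bacteroides held 23.4% to 35.6% and Blautia 9.63% to 17.8%, against 3.14% to 6.80% and 0.186% to 0.710% in PAE males 16 to 19 and 25. With PAE males 16 to 19 alone neither genus was called: edgeR called 0 genera, and 2 of the 13 genera called in all males had an unadjusted p under 0.05. All 13 passed with PAE males 20 to 25 alone.

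**Figure D1:**
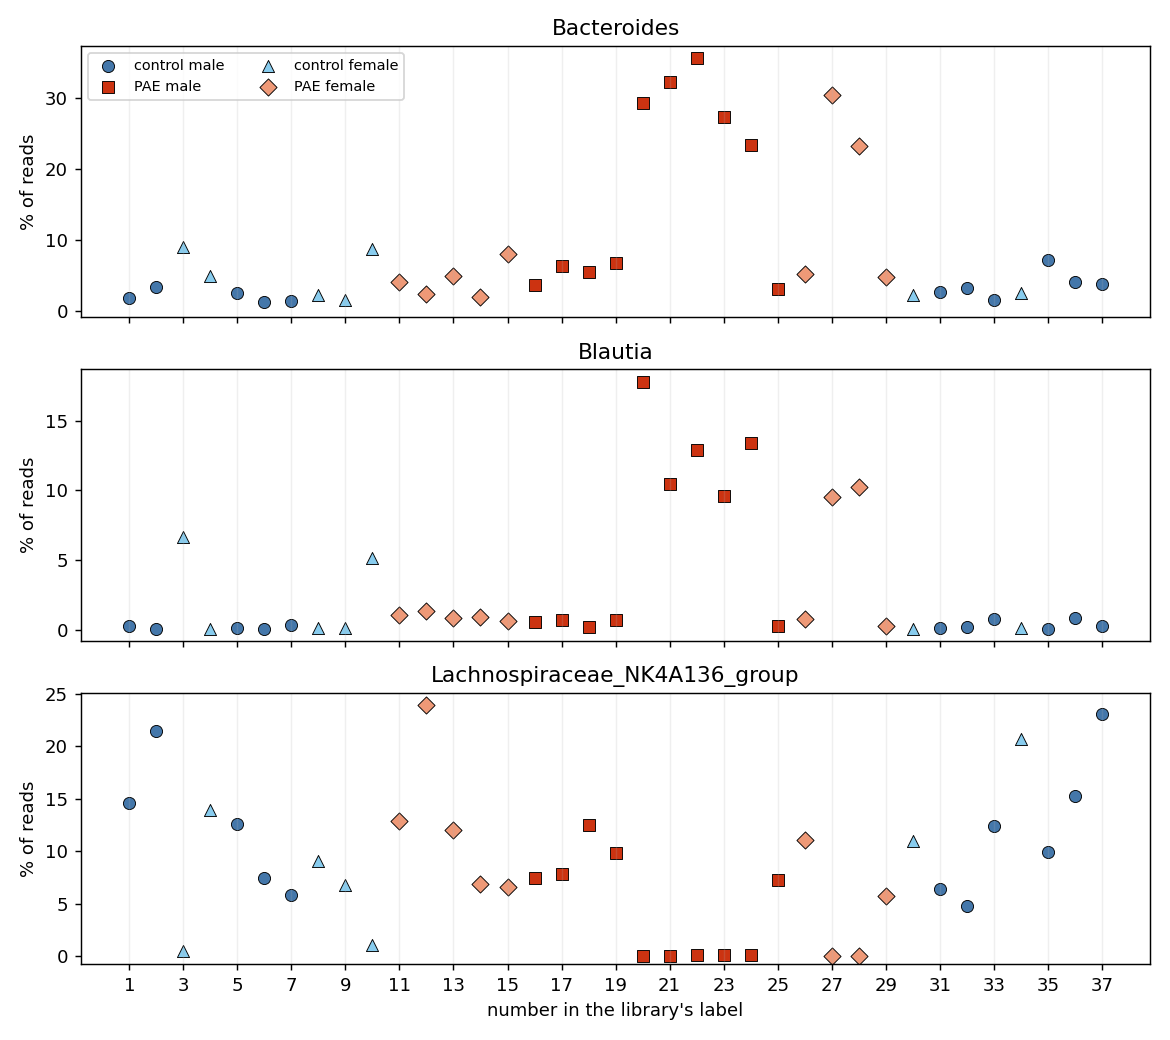
Percent of reads in Bacteroides, Blautia and Lachnospiraceae_NK4A136_group in each of the 37 libraries (y axes), by the number in the library's label (x axis). Points are single libraries, coloured by group; PAE males 20 to 24 and PAE females 27 and 28 hold the highest Bacteroides shares, from 23.3% to 35.6%.

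Further Firmicutes rose in PAE males from very low control levels. Hungatella, a spore-forming Lachnospiraceae genus, rose from 0.00156% ± 0.00156 to 0.865% ± 0.981 (553-fold, edgeR adjusted p = 0.00189), and Coprobacillus from 17 reads over 3 of 11 controls to 0.777% ± 1.06, with reads in 8 of 10 PAE males (edgeR adjusted p = 0.000650). Both rises lay in PAE males 20 to 24, with 0.942% to 2.46% Hungatella and 0.490% to 2.87% Coprobacillus. The other PAE males held at most 0.00162% and 0.00213%, the latter below the highest control (0.00305%). With PAE males 16 to 19 alone the log2 fold change of Hungatella was negative. Flavonifractor, a flavonoid-degrading butyrate producer, Clostridioides, the genus of C. difficile, and Robinsoniella had 0 reads in control males. Their PAE shares of 0.107% ± 0.133 (5 of 10 libraries), 0.0975% ± 0.140 (4 of 10) and 0.0415% ± 0.0627 (5 of 10) were at least 1736-fold, 1589-fold and 676-fold higher (edgeR adjusted p 0.00295, 0.00305 and 0.00698). All of these libraries were again among PAE males 20 to 24. Without PAE male 21 the Robinsoniella share was 0.0243% ± 0.0335, at least 396-fold higher (edgeR adjusted p = 0.0137). Lachnoclostridium rose from 0.456% ± 0.244 to 1.60% ± 0.822 (log2 fold change 2.50, SE 0.71, 10 of 10 above the control median, edgeR adjusted p = 0.0110). Leaving out any 1 of control males 1, 7, 31, 35 and 36, control females 8 and 9, or PAE males 16, 18, 19, 20 and 25 ended the Lachnoclostridium call (edgeR adjusted p up to 0.132). The [Clostridium]_innocuum_group rose from 0.00110% ± 0.00165 to 0.118% ± 0.135 (108-fold, edgeR adjusted p = 0.0188), a call lost without any 1 of control males 1, 31, 35 or 36 (up to 0.0618). Its rise also lay in PAE males 20 to 24 (0.161% to 0.360%). The other PAE males held at most 0.00121%, below the highest control male (0.00450%). Turicibacter was called at 0.653% ± 2.05 against 0.000508% ± 0.00138 (edgeR adjusted p = 0.00189) on 6.49% of reads in PAE male 25, without which its adjusted p was 0.231. Clostridium_sensu_stricto_1, outside the rule for named taxa and named after its values were seen, was the remaining genus called higher and stayed called in 10 of 37 fits that left out 1 library (edgeR adjusted p up to 0.132).

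The 2 genera that fell in PAE males were Intestinimonas, a butyrate producer, and F082, a Bacteroidales lineage. Intestinimonas held 0.0688% ± 0.0708 of reads in control males and 3 reads over the 10 PAE males, a pooled share 760-fold lower (counting interval 260 to 3685, edgeR adjusted p = 0.000650), with 7 of 11 controls above all PAE males. F082 held 0.417% ± 0.996 in controls and 6 reads in 2 of 10 PAE males (edgeR adjusted p = 0.00104), with 4 controls above all PAE males. Those control reads lay in control males 31 (0.754%), 32 (0.512%) and 33 (3.32%), with at most 0.00203% in the other 8. Without control male 33 the control mean of F082 was 0.127% ± 0.273 (n = 10) and its log2 fold change -8.97 in place of -10.58 (edgeR adjusted p = 0.00304), and with controls 1 to 10 alone it was not called. In total 13 of 111 genera were called in males, 11 higher and 2 lower, with 31 at an unadjusted p under 0.05. DESeq2 called 18 (12 higher, 6 lower) and limma on centred log-ratios 29 (15 higher, 14 lower), so the share of calls that were higher fell from 84.6% to 66.7% and 51.7%. Of the 13 genera, DESeq2 called 13 and limma 10, while limma with label-number runs as a random block called 0 of 111. With the block all 13 kept their direction and 2 had an unadjusted p under 0.05. The limma log2 fold change of Bacteroides was 2.83 (SE 0.90) without and 2.61 (SE 1.49) with the block, and that of Blautia 4.40 (SE 1.28) and 4.09 (SE 2.31). Over the 13 genera the SE grew by a median of 1.69-fold and the log2 fold change was multiplied by a median of 0.898, so the calls ended mainly through the wider SE. No run holds both exposures and each exposure has 2 runs, so the block fit has little power. Its 0 calls do not decide between exposure and run. With controls 1 to 10 alone 2 of the 13 were called, and without the 9 libraries that stand apart 1, Turicibacter.

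Other abundant genera of males did not pass. The fibre-degrading Muribaculaceae held 30.9% ± 5.83 in controls and 24.4% ± 9.65 in PAE (edgeR adjusted p = 0.788). Lachnospiraceae_NK4A136_group held 12.2% ± 6.16 and 4.51% ± 4.93 (log2 fold change -1.65, edgeR adjusted p = 0.212), with 0.011% to 0.117% in PAE males 20 to 24 and 7.25% to 12.5% in the other 5. Unclassified Lachnospiraceae (6.67% and 2.69%), Alistipes (4.62% and 2.35%), Prevotellaceae_UCG-001 (3.46% and 3.88%), Lactobacillus (3.38% and 2.05%), Helicobacter (2.68% and 4.19%) and Parabacteroides (2.26% and 3.70%) had edgeR adjusted p from 0.212 to 0.660. Among phyla, Bacteroidota held 51.6% ± 7.0 and 59.0% ± 6.82 (edgeR adjusted p = 0.117), Firmicutes 41.6% ± 4.97 and 30.8% ± 9.50 (0.909), and Proteobacteria 1.23% ± 0.644 and 3.95% ± 3.71 (0.0807). The Firmicutes share was 1.35-fold lower in PAE males, with 6 of 10 below every control. Its log2 fold change after TMM scaling was only -0.06, so this test does not show the fall in share. Campilobacterota held 2.68% ± 2.67 and 4.19% ± 1.66, Desulfobacterota 1.28% ± 1.0 and 1.15% ± 0.544, and Deferribacterota 0.800% ± 1.33 and 0.516% ± 0.659, none of which passed. Patescibacteria, small-genome bacteria, was the 1 phylum of 15 that passed, at 0.0158% ± 0.0282 in controls and 4 reads in 1 of 10 PAE males (edgeR adjusted p = 0.00953). Control males 35 to 37 held 1038 of its 1063 control male reads. Without control male 37 the control mean was 0.00863% ± 0.0161 (edgeR adjusted p = 0.0261), and Patescibacteria was not called with PAE males 16 to 19 alone. Of 60 families, Bacteroidaceae and Erysipelatoclostridiaceae rose and F082 fell. Erysipelatoclostridiaceae went from 0.0203% ± 0.0319 to 0.937% ± 1.09 (46.2-fold, edgeR adjusted p = 0.00292), and its control mean was 0.0119% without control male 1 (0.00139).

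Of the 16 lists, 2 changed in males. Butyrate producers fell from 16.96% ± 6.63 of reads (n = 11) to 7.36% ± 6.40 (n = 10; permutation p = 0.00432, adjusted p = 0.0346 over the lists). Of their 9 tested members Flavonifractor rose and Intestinimonas fell, also when adjusted over the list alone, while Odoribacter stood at 1.91% ± 0.744 and 1.0% ± 1.06 (edgeR adjusted p = 0.159). The summed share is set largely by Lachnospiraceae_NK4A136_group, whose own fall was not called (log2 fold change -1.65, edgeR adjusted p = 0.212). Propionate and succinate producers rose from 11.8% ± 3.70 to 26.3% ± 13.8 (permutation p = 0.00360, adjusted p = 0.0346), and Bacteroides was the 1 member called of 4, over all genera and adjusted over the list alone. Neither list passed with PAE males 16 to 19 alone, with controls 1 to 10 alone or on ranks.

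The summed share of Lachnospiraceae was 23.2% ± 5.61 and 17.8% ± 3.41 (permutation p = 0.0181, adjusted p = 0.0964), although 4 of its 20 genera rose and 0 fell by edgeR, the same 4 and 0 when adjusted over the list alone. Oscillospirales families held 6.64% and 4.12% (adjusted p = 0.134), with Flavonifractor called higher, Intestinimonas lower, and Anaerotruncus at 0.0406% and 0.00554% (edgeR adjusted p = 0.0743). Erysipelotrichales families held 3.467% and 2.999% (adjusted p = 0.845), with 3 of 7 members called higher, and 4 higher and 1 lower when adjusted over the list alone. Muribaculaceae (31.5% and 24.7%, adjusted p = 0.194, members Muribaculaceae and Muribaculum), Rikenellaceae (6.55% and 4.11%, 0.134, Alistipes and Rikenellaceae_RC9_gut_group) and Prevotellaceae (5.91% and 8.07%, 0.221, Prevotellaceae_NK3B31_group, Alloprevotella and Prevotellaceae_UCG-001) had no member called by edgeR, over all genera or adjusted over the list alone. The same held for lactic acid bacteria (3.44% and 2.12%, adjusted p = 0.466, Enterococcus, Lactobacillus and Streptococcus), bifidobacteria (0.130% and 0.235%, 0.924), mucus-associated bacteria (3.48% and 4.71%, 0.545, Helicobacter and Mucispirillum) and sulfate and sulfite reducers (1.28% and 1.15%, 0.845, Bilophila, Desulfovibrio and unclassified Desulfovibrionaceae). Bilophila, at 0.0462% and 0.143%, was the member of these lists with an unadjusted p under 0.05 (0.0351, edgeR adjusted p = 0.139). The bifidobacteria of PAE males rested on PAE male 25 (2.32%, at most 0.0140% in the others): without it Bifidobacterium was called lower in PAE males by edgeR (log2 fold change -5.94, adjusted p = 0.0374), as it was by DESeq2 with all males (-4.79, adjusted p = 0.00463). Enterobacterales (0.0169% and 0.0189%, with Escherichia-Shigella), segmented filamentous bacteria (Candidatus_Arthromitus, 0.0488% and 0.0387%) and plastid and mitochondrial reads (0.0104% and 0.0117%) each had an adjusted p of 0.845. Reagent and skin contaminants held 0.0109% and 0.0215% (adjusted p = 0.265), with Burkholderia-Caballeronia-Paraburkholderia, Sphingomonas and Staphylococcus not called.

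Among 553 ASVs, 67 were called in males, 23 higher and 44 lower, with 121 at an unadjusted p under 0.05 and 82 called by DESeq2. The 44 lower ASVs included 11 of unclassified Lachnospiraceae, 8 of Muribaculaceae and 3 of unclassified Oscillospiraceae, and 31 of the 44 had no read in any PAE male. An ASV of unclassified Rhodospirillales went from 0.232% ± 0.278 in controls to 3 reads, and 2 of unclassified Lachnospiraceae from 0.0440% and 0.0239% to 0 reads (at least 486-fold and 264-fold lower, edgeR adjusted p 0.00326 and 0.00443). The 23 higher ASVs included 5 of Lachnoclostridium and 4 of Muribaculaceae. A Blautia ASV rose from 0.00573% ± 0.00362 to 3.14% ± 3.45, a Muribaculaceae ASV from 0.000234% to 0.732% ± 1.32 in 5 of 10 PAE males, and another from 0 reads to 0.0489% ± 0.0539 in 7 of 10 (at least 797-fold, edgeR adjusted p = 0.00315 for each). With PAE males 16 to 19 alone 2 ASVs were called, without the 9 libraries that stand apart 2, with controls 1 to 10 alone 10 and with controls 30 to 37 alone 170. Limma called 95 ASVs, and 0 with label-number runs as a random block.

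Community composition differed between PAE and control males (R2 of Bray-Curtis distances 15.3%, permutation p = 0.00179), with mean distance to the centroid of 0.421 ± 0.0538 and 0.475 ± 0.0713 (permutation p = 0.0688). The Shannon index was 4.60 ± 0.320 in control males (n = 11) and 4.13 ± 0.535 in PAE males (n = 10), a difference of -0.47 (permutation p = 0.0254). On genera in place of ASVs the Shannon difference was smaller and did not pass. Observed ASVs fell from 548 ± 114 to 362 ± 148 (permutation p = 0.00577), and were 190 to 260 in PAE males 20 to 24 against 439 to 541 in the other 5. The log2 ratio of Firmicutes to Bacteroidota was -0.31 ± 0.35 and -0.99 ± 0.61, lower by 0.68 in PAE (permutation p = 0.00635). With PAE males 16 to 19 alone none of these passed: R2 was 10.2% (exact permutation p = 0.139), and the differences were 0.01 in the Shannon index (0.962), -59.8 observed ASVs (0.336) and -0.32 in the phylum ratio (0.183). That cut leaves 4 PAE males, so it does not show that they match controls. Against either run of control males alone their composition differed. R2 was 20.6% with controls 1 to 10 (exact permutation p = 0.0397) and 27.05% with controls 30 to 37 (0.0333). With controls 30 to 37 alone the Shannon (-0.34, exact permutation p = 0.183), observed ASV (0.0659) and ratio (-0.58, 0.0619) differences did not pass.

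**Figure D2:**
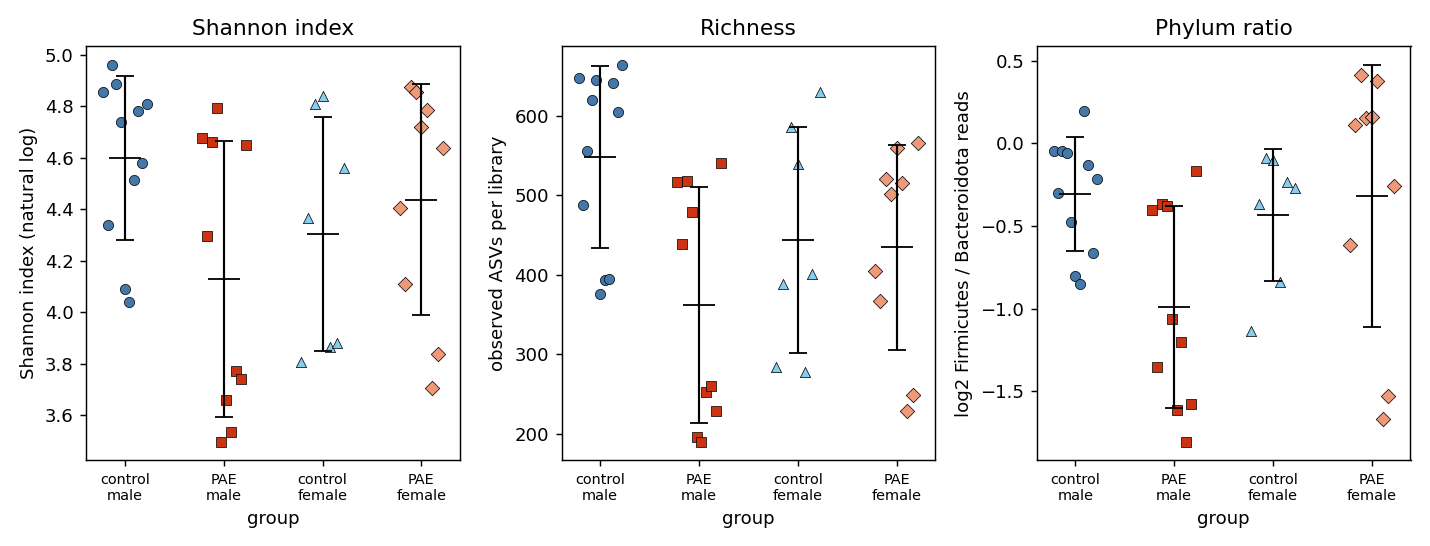
Shannon index, observed ASVs and log2 ratio of Firmicutes to Bacteroidota reads (y axes) by group (x axis). Points are libraries, and bars the mean and SD; observed ASVs run from 190 to 260 in PAE males 20 to 24 and from 439 to 541 in PAE males 16 to 19 and 25.

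In females, 3 of 111 genera were called. Intestinimonas fell from 0.0241% ± 0.0388 in controls (n = 7) to 3 reads over 9 PAE females, a pooled share 351-fold lower (counting interval 120 to 1703, edgeR adjusted p = 0.00888), the 1 genus called in both sexes. Without control female 8 its control mean was 0.0105% ± 0.0163, 154-fold above the pooled PAE share (n = 6, edgeR adjusted p = 0.0211). Unclassified Christensenellaceae fell from 203 reads in 3 of 7 controls (0.0116% ± 0.0291) to 0 reads (at least 169-fold, edgeR adjusted p = 0.0141), a call lost without control female 10 (0.132), where the control mean was 0.000605% ± 0.00111 (n = 6) and the bound at least 8.83-fold. Sphingomonas, a common reagent contaminant, rose from 0 reads to 64 reads in 8 of 9 PAE females (0.00238% ± 0.00183, at least 28.3-fold, edgeR adjusted p = 0.0202). In females 11 genera reached an unadjusted p under 0.05, and the calls were 1 higher and 2 lower (33.3% higher) by edgeR, 2 and 2 with TMMwsp scaling (50%), 4 and 2 by DESeq2 (66.7%) and 1 and 0 by limma on centred log-ratios. Of the 3 genera, TMMwsp called 3, DESeq2 called 2 and limma 0. With PAE females 11 to 15 alone 1 genus was called, Sphingomonas, and with 26 to 29 alone 7, none of them among the 3. In the limma fit with label-number runs as a random block 0 were called.

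The genera that rose in males did not pass in females: Bacteroides held 4.52% ± 3.17 and 9.49% ± 10.1 (n = 7 and 9, log2 fold change 1.37, edgeR adjusted p = 0.495), Blautia 1.75% ± 2.88 and 2.84% ± 4.01 (0.944), Hungatella 0.000947% and 0.375% (0.0555) and Coprobacillus 0.000461% and 0.104% (0.0714). In PAE females 27 and 28 Bacteroides held 30.3% and 23.3% and Blautia 9.55% and 10.2%. Muribaculaceae held 32.5% ± 6.16 and 25.6% ± 7.72 (edgeR adjusted p = 0.495), Lachnospiraceae_NK4A136_group 8.999% ± 7.14 and 8.77% ± 7.36 (0.968) and Lactobacillus 8.22% ± 2.84 and 7.70% ± 5.58 (0.968). Unclassified Lachnospiraceae (2.90% and 5.57%), Helicobacter (3.21% and 4.34%), Alistipes (2.60% and 3.29%), Parabacteroides (2.76% and 3.17%) and Prevotellaceae_UCG-001 (3.98% and 2.46%) did not pass either. Bacteroidota held 52.8% ± 3.22 and 50.1% ± 10.6, Firmicutes 39.8% ± 7.90 and 41.5% ± 12.1, Proteobacteria 1.71% and 1.37%, Campilobacterota 3.21% and 4.34%, Desulfobacterota 1.13% and 1.16%, and Deferribacterota 0.0804% and 0.761%, all with edgeR adjusted p above the threshold. Chloroflexi was the 1 phylum of 15 called, at 0.00682% ± 0.0101 in controls and 9 reads in PAE females (edgeR adjusted p = 0.0324). Its call ended in 10 of 37 fits that left out 1 library (edgeR adjusted p up to 0.167, without control female 8, where the control mean was 0.00333%). Christensenellaceae was the 1 family of 60, at 0.0157% ± 0.0293 and 0 reads (at least 229-fold lower, edgeR adjusted p = 0.0476). That call ended in 16 of 37 such fits (up to 0.131), and without control female 10 the control mean was 0.00541% ± 0.0120 and the bound at least 78.9-fold.

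None of the 16 lists changed in females (exact permutation p from 0.0784 to 0.978, adjusted p from 0.764 to 0.978), with 0 at an unadjusted p under 0.05. Butyrate producers held 12.4% and 12.9%, propionate and succinate producers 11.3% and 16.9%, Muribaculaceae 32.9% and 26.01%, Lachnospiraceae 19.1% and 21.9%, Oscillospirales families 4.31% and 5.16% and Erysipelotrichales families 4.36% and 2.60%. Lactic acid bacteria held 8.31% and 7.78%, bifidobacteria 0.104% and 0.0518%, mucus-associated bacteria 3.29% and 5.11%, with Mucispirillum at 0.0804% and 0.761%, and sulfate and sulfite reducers 1.13% and 1.16%. Enterobacterales held 0.0212% and 0.0222%, segmented filamentous bacteria 0.0376% and 0.0312%, Rikenellaceae 4.46% and 5.70%, Prevotellaceae 6.38% and 3.96%, reagent and skin contaminants 0.0153% and 0.0240%, and plastid and mitochondrial reads 0.00649% and 0.00888%. Intestinimonas and Sphingomonas were the list members called by edgeR over all genera. When adjusted over the list alone, Hungatella was also called higher among 20 Lachnospiraceae genera and Coprobacillus among 7 Erysipelotrichales genera. Both lay in PAE females 27 and 28, with at most 0.00431% and 0.00335% in the other 7. Without PAE female 28 the Hungatella mean was 0.115% in place of 0.375%, and without PAE female 27 the Coprobacillus mean was 0.0115% in place of 0.104%. Neither call adjusted over the list alone was then made (edgeR adjusted p 0.105 and 0.129). Other members with the smallest p did not pass: Flavonifractor, Butyricicoccus, Alloprevotella, Muribaculum, Lachnospiraceae_UCG-004, Lachnoclostridium, Anaerotruncus, unclassified Ruminococcaceae, Turicibacter, Erysipelatoclostridium, Streptococcus, Enterococcus, Bifidobacterium, Bilophila, Desulfovibrio, unclassified Desulfovibrionaceae, Escherichia-Shigella, Candidatus_Arthromitus, Rikenellaceae_RC9_gut_group, Prevotellaceae_NK3B31_group, Pseudomonas and Staphylococcus (edgeR adjusted p from 0.203 to 0.995).

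In females 68 ASVs were called, 22 higher and 46 lower, with 99 at an unadjusted p under 0.05 and 63 called by DESeq2. Limma called 9, and 0 with label-number runs as a random block. By edgeR 6 were called with controls 1 to 10 alone and 0 with PAE females 11 to 15 alone or without the 9 libraries that stand apart. The 46 lower ASVs included 9 of Muribaculaceae, 7 of unclassified Lachnospiraceae and 5 of unclassified Oscillospiraceae, and 34 of the 46 had no read in any PAE female. A Lachnospiraceae_NK4A136_group ASV went from 1.09% ± 1.91 in 3 of 7 controls to 0 reads (at least 15964-fold, edgeR adjusted p = 0.0158), a Lachnospiraceae_UCG-006 ASV from 0.0688% to 0 reads (at least 1004-fold, 0.0158), and the Rhodospirillales ASV from 0.281% ± 0.342 to 8 reads (0.0137). Higher from 0 reads were a Desulfovibrio_fairfieldensis ASV at 0.0420% ± 0.0760 (5 of 9 libraries), an unclassified Lachnospiraceae ASV at 0.126% ± 0.226 (7 of 9) and a Muribaculaceae ASV at 0.0243% ± 0.0208 (6 of 9), at least 498-fold, 1501-fold and 289-fold (edgeR adjusted p = 0.0185 for each). Of the 67 and 68 ASVs, 43 were called in both sexes, all in the same direction (35 lower, 8 higher), against 8.24 for independent lists. The lists are not independent, since males and females of an exposure come from the same runs of label numbers. With controls 1 to 10 alone 4 ASVs were called in both sexes. With controls 30 to 37 alone, which leaves 2 control females, 54 were, 53 of them in the same direction. The count was 0 with PAE libraries 11 to 19 alone, without the 9 libraries that stand apart, and by limma with label-number runs as a random block. DESeq2 called 38 in both sexes, 35 of them in the same direction. For 24 of the 35 lower ASVs, over 90% of the control reads lay in controls 30 to 37.

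Community composition of females did not pass (R2 8.59%, exact permutation p = 0.205), but did with controls 30 to 37 alone (n = 2, 18.3%, 0.0364) and with PAE females 26 to 29 alone (n = 4, 18.7%, 0.0303). The Shannon index was 4.30 ± 0.454 in controls (n = 7) and 4.44 ± 0.449 in PAE (n = 9; exact permutation p = 0.557), and observed ASVs were 444 ± 143 and 434 ± 129 (exact permutation p = 0.892). The log2 ratio of Firmicutes to Bacteroidota was -0.43 ± 0.40 and -0.32 ± 0.79 (exact permutation p = 0.728), and distances to the centroid were 0.433 and 0.421 (exact permutation p = 0.796).

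**Figure D3:**
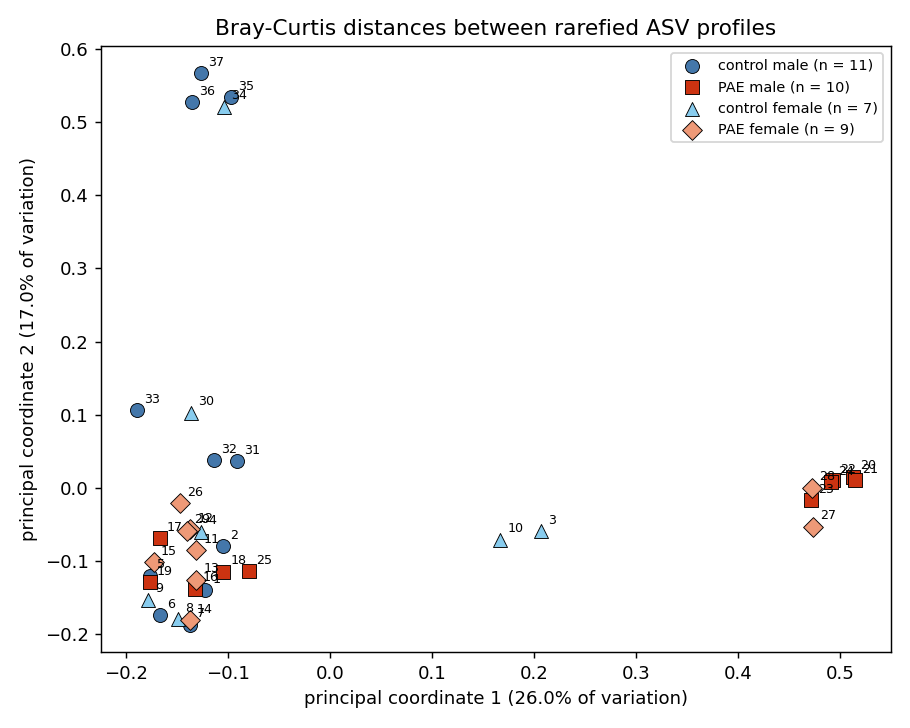
Principal coordinates of Bray-Curtis distances between rarefied ASV profiles, with the share of variation on each axis (26.03% and 16.96%). Points are libraries, coloured by group and numbered by label; PAE males 20 to 24 lie beside PAE females 27 and 28, and controls 34 to 37 of both sexes lie together.

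The effect of exposure differed between the sexes for 2 of 111 genera. Robinsoniella had no read in control males and was in 5 of 10 PAE males, and held 0.233% ± 0.421 in control females (2 of 7) and 0.0185% ± 0.0514 in PAE females (interaction edgeR adjusted p = 0.0359). Unclassified Christensenellaceae stood at 33 and 63 reads in control and PAE males, and at 203 and 0 reads in control and PAE females (interaction edgeR adjusted p = 0.0359). Both calls were fragile: leaving out 1 library ended the first in 18 of 37 fits (edgeR adjusted p up to 0.1499) and the second in 19 of 37 (up to 0.9997). Robinsoniella had reads in exactly the 9 libraries that stand apart. Neither genus was called by limma, with or without label-number runs as a random block. By edgeR with controls 1 to 10 or 30 to 37 alone neither was called. The same held with PAE libraries 11 to 19 or 20 to 29 alone, or without those 9 libraries. For Robinsoniella the fit without those 9 libraries could make no call, since no read of it was left. Lachnoclostridium (difference of log2 fold changes 3.55) and F082 had an interaction edgeR adjusted p of 0.0512, Sphingomonas 0.0948 and [Clostridium]_innocuum_group 0.0966, with 13 genera at an unadjusted p under 0.05 and 7 called by DESeq2. For Bacteroides the interaction was 1.94 on the log2 scale (edgeR adjusted p = 0.421), so its rise in males was not shown to differ from females. No ASV passed (0 of 553 by edgeR, 68 at an unadjusted p under 0.05, 35 by DESeq2, 13 with TMMwsp).

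The Shannon index showed an interaction of -0.60 (permutation p = 0.0488) and the log2 phylum ratio one of -0.80 (0.0419), both more negative in males. The interaction test of the ratio was not among those fixed before the data were examined. Observed ASVs (-177, permutation p = 0.0540) and composition (R2 3.68%, 0.162) did not pass. With PAE libraries 11 to 19 alone the Shannon interaction was -0.28 (permutation p = 0.344) and that of the ratio -0.80 (0.0206). With PAE libraries 20 to 29 alone they were -0.73 (permutation p = 0.0389) and -0.59 (0.180), and without the 9 libraries that stand apart neither passed. No list showed an interaction after adjustment (0 of 16, 3 at an unadjusted p under 0.05), the smallest p being that of Lachnospiraceae (-8.23 percentage points, permutation p = 0.0252, adjusted p = 0.203).

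Between the sexes, 5 of 111 genera were called in controls. F082 (0.417% ± 0.996 in 11 males and 0.000449% in 7 females, edgeR adjusted p = 0.0235) and Sphingomonas (68 and 0 reads, 0.0235) were higher in males. Lachnoclostridium (0.456% ± 0.244 and 3.10% ± 4.48, edgeR adjusted p = 0.0116), Robinsoniella (0 reads and 0.233% ± 0.421 in 2 of 7, 0.0120) and [Clostridium]_innocuum_group (0.00110% and 0.262% ± 0.445, 0.0290) were higher in females. The Lachnoclostridium call ended without control female 3 (edgeR adjusted p = 0.0592), the Sphingomonas call without control female 3 or 34 (up to 0.0628), the F082 call without control female 3, 8, 9, 10 or 34 (up to 0.0769) and that of [Clostridium]_innocuum_group in 14 of 37 fits (up to 0.0934). Without control female 10 the Lachnoclostridium share of control females was 1.78% (edgeR adjusted p = 0.04997), that of Robinsoniella 0.0962% (0.0465) and that of [Clostridium]_innocuum_group 0.157% (0.0618). The last was 0.149% without control female 3 (0.0934), and without control male 33 the F082 share of control males was 0.127% (0.0481). The F082 reads lay in control males 31 to 33. The run 30 to 37 held 6 of 11 control males and 2 of 7 control females, and none of the 5 genera was called with controls 1 to 10 alone, with controls 30 to 37 alone or by limma with label-number runs as a random block. Mucispirillum, unclassified Erysipelotrichaceae and Paludicola did not pass (edgeR adjusted p 0.515, 0.714 and 0.0780). In controls 13 genera reached an unadjusted p under 0.05, DESeq2 called 10 and limma 0, and without the 9 libraries that stand apart, control females 3 and 10 among them, edgeR called 0. Robinsoniella had no read left in that fit. In PAE libraries 0 of 111 genera were called by edgeR, with 9 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma. The smallest adjusted p of a genus was 0.143, for unclassified Caldilineaceae, Erysipelatoclostridium (0.158% ± 0.213 in males and 0.00289% in females) and Gastranaerophilales (0.0781% and 0.560%). Lactobacillus held 2.05% and 7.70% (log2 fold change -1.60, edgeR adjusted p = 0.216), and Romboutsia (0.216), unclassified Christensenellaceae (0.181), WD2101_soil_group (0.391) and Marvinbryantia (0.601) did not pass. At other ranks, 1 of 15 phyla was called between the sexes in PAE: Chloroflexi, at 0.00570% ± 0.00820 in males and 0.000167% ± 0.000380 in females (118 and 9 reads, edgeR adjusted p = 0.0416; 3 phyla by DESeq2 and 0 with TMMwsp). It stayed called in 24 of 37 fits that left out 1 library (edgeR adjusted p up to 0.103). In controls the family F082 was the 1 of 60 called (edgeR adjusted p = 0.0458), in 20 of 37 such fits (up to 0.1196), and 5 of 553 ASVs were called, all higher in females. These were 3 ASVs of Lachnoclostridium, 1 of Blautia and 1 of Robinsoniella, and 3 of the 5 had reads in control females 3 and 10 alone. DESeq2 called 32 ASVs there and limma 0, and edgeR called 0 with controls 1 to 10 alone, with controls 30 to 37 alone or without the 9 libraries that stand apart. In PAE edgeR called 0 of 60 families (7 at an unadjusted p under 0.05, 4 by DESeq2) and 0 of 553 ASVs (31, 17 by DESeq2 and 1 by limma), and in controls 0 of 15 phyla (0, 0 by DESeq2). The difference in composition between the sexes did not pass in controls (R2 5.94%, exact permutation p = 0.412) or in PAE (10.7%, 0.0735), and neither did that in the Shannon index (0.123 and 0.192) or observed ASVs (0.104 and 0.268). These tests do not show that the sexes are alike.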

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

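The tests of label numbers and other splits in this part were chosen only after the results were seen. The fit with depth as a covariate was fixed before, while its use to weigh an explanation came after. A single library lay far from the rest of its group in 20 of 105 combinations of a group and a measure, where chance gives about 1 in 20. PAE male 17 held 46.8% Muribaculaceae (47.97% over the whole family) against 16.0% to 31.1% in the other PAE males, and control female 30 held 45.3% (45.4%) against 26.8% to 33.5%. PAE male 25 held 7.38% Lactobacillus (7.43% for all lactic acid bacteria), 15.03% Erysipelotrichales families against at most 4.17% and 2.32% bifidobacteria against at most 0.0140%. PAE female 13 held 10.1% Helicobacter, all of its Campilobacterota, against 1.95% to 5.29%, and 12.1% mucus-associated bacteria. PAE female 14 held 11.8% Erysipelotrichales families, 0.261% bifidobacteria and 0.0924% Enterobacterales. Control female 3 held 2.97% Desulfobacterota, all of them sulfate and sulfite reducers, against 0.213% to 1.204%, and control female 34 held 26.2% Lachnospiraceae against 16.0% to 19.4%. Segmented filamentous bacteria reached 0.210% in control female 9 and 0.0930% in PAE female 29, and reagent and skin contaminants 0.0636% in control female 10 against 0.00259% to 0.0101%.

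Part of the male result followed the label numbers within the exposed group: PAE males 20 to 25 against PAE males 16 to 19 gave 16 called genera of 111 (34 at an unadjusted p under 0.05). These held 8 of the 13 male genera, an overlap partly built in because both comparisons use PAE males 20 to 25. Intestinimonas, F082, Clostridioides, Turicibacter and Lachnoclostridium were not called there, which does not show that they were alike across those numbers. Among PAE males, Clostridioides had reads in 20 to 23 alone (0.0992% to 0.352%). Lachnoclostridium held 2.15% to 2.71% in 20 to 24 and 0.567% to 1.15% in 16 to 19 and 25. The Turicibacter call rested on PAE male 25. An exposure effect of like size in every PAE male, with no other difference between them, is argued against: over all ASVs, PAE males 1 number apart were closer than other pairs (Bray-Curtis 0.449 ± 0.209 over 9 pairs and 0.639 ± 0.181 over 36, permutation p = 0.0064). Library depth is argued against as well, since 17 genera were called with log2 total reads as a covariate. A cage, litter or batch shared by libraries with neighbouring label numbers is a candidate explanation for part of the male difference, while an exposure effect of like size on top of differences between number runs, or one that reached some litters more than others, stays open and was not tested, since dams and litters are not given in the sources used here.

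The effect of exposure differed between the sexes for the Shannon index (-0.60, permutation p = 0.0488), for the log2 ratio of Firmicutes to Bacteroidota (-0.80, 0.0419), and for Robinsoniella and unclassified Christensenellaceae (edgeR adjusted p = 0.0359 each). Of these tests, that of the ratio was not fixed before the data were examined. Depth is argued against for the Shannon index, since the interaction was -0.60 both in the counts as deposited and after rarefaction to one depth. PAE females carry the numbers 11 to 15 and 26 to 29 and PAE males 16 to 25, so the sexes sample the number runs unequally. The Shannon interaction was -0.28 (SE 0.27) with PAE libraries 11 to 19 alone, which excludes neither 0 nor the full value, and -0.73 (permutation p = 0.0389) with 20 to 29 alone, so sex and label number cannot be told apart for it. A true difference between the sexes stays open.

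In 100 splits of the libraries, the real one included, only the real one reached the ASV count of males (67, highest other 46). The same held for females (68, highest other 54). This argues against a chance split of independent libraries for both counts. However, 1 in 100 is the smallest share these splits can give, and it was not corrected for the number of counts tested. For the 5 genera between the sexes in controls 4 splits, the real one included, were as large, and 2 lay above the real count (highest other 6). Many such counts were tested without correction, and the ASVs and family of that comparison did not exclude chance. Chance is therefore not excluded for these genera. None of the 5 was called without the 9 libraries that stand apart, where Robinsoniella had no read left, or by limma with label-number runs as a random block. These splits treat libraries as independent, although neighbouring label numbers resemble each other and each run of numbers holds 1 exposure. With the 4 runs as a random block limma called 0 ASVs in either sex, against 95 in males and 9 in females without the block, so a run effect is not excluded. Chance cannot be excluded for the 13 genera in males (6 splits as large, highest other 17), the 3 in females (21 splits, highest other 20) or the 2 of the interaction (19 splits, highest other 12). Where 0 genera (male against female in PAE) or 0 ASVs (interaction) were called, all 100 splits reach that count by construction, so the splits say nothing of chance there (highest other 21 and 57). Chance cannot be excluded either for the 1 phylum (18 splits, highest other 4) and 3 families (8 splits, highest other 8) in males, or for the 1 phylum and 1 family in females (10 splits each, highest other 2 and 4). Between the sexes it cannot be excluded for the 5 ASVs (28 splits, highest other 65) and 1 family (24 splits, highest other 2) in controls or the 1 phylum in PAE (13 splits, highest other 3). Other splits that call several times the real count, such as 20 genera against 3, point to a structure among the libraries besides exposure and sex.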

How the results depend on the processing

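The fits with PAE libraries 11 to 19 or 20 to 29 alone, without the 9 libraries that stand apart, and with label-number runs as a random block were chosen only after the results were seen, as were those of phyla and families that left out 1 library. Counts of genera are given in the order males, females, interaction, sex in controls and sex in PAE, where the reported counts are 13, 3, 2, 5 and 0. DESeq2 gave 18, 6, 7, 10 and 2, limma on centred log-ratios 29, 1, 0, 0 and 0, no filter 122, 43, 33, 22 and 15, and the stricter filter, which tests fewer genera, 2, 0, 0, 4 and 0. TMMwsp gave 14 and 4, and totals alone 12 and 3, in males and females. All rows gave 12 and 3 there, and the libraries of 1 sex alone 14 and 2. TMMwsp and totals moved the median log2 fold change of all genera by 0.12 and -0.14 in males and by 0.27 and 0.27 in females. Depth as a covariate gave 17, 3 and 1 for the first 3 counts, controls 1 to 10 alone 2, 1 and 0, and controls 30 to 37 alone 21, 2 and 0. Either run of controls alone gave 0 for sex in controls. PAE libraries 11 to 19 alone gave 0, 1 and 0, and 20 to 29 alone 22, 7 and 0. Without the 9 libraries the counts were 1, 0, 0, 0 and 0, and with the random block (correlation 0.372) 0, 0, 0, 1 and 1. Leaving out 1 library gave 10 to 15 genera in males and 2 to 5 in females. The cause was not tested.

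ASV counts were 67 in males, 68 in females and 0 for the interaction. They were 95, 9 and 0 by limma, 551 and 449 in the sexes with the looser filter, 8 and 2 with the stricter, 10 and 6 with controls 1 to 10, 170 and 61 with controls 30 to 37, 2 and 0 with PAE 11 to 19, 124 and 9 with PAE 20 to 29, 2 and 0 without the 9 libraries, and 0 and 0 with the random block (correlation 0.350). For the interaction TMMwsp gave 13 and DESeq2 35. Between the sexes in controls the 5 ASVs became 7 with TMMwsp, 4 with totals alone, 32 by DESeq2, 13 with the looser filter and 1 with the stricter, and 0 by limma, with the random block, with either run of controls alone or without the 9 libraries. The 1 family there became 0 without the 9 libraries. The 1 phylum in PAE became 3 by DESeq2 and 0 with TMMwsp, with either run of PAE libraries alone or without the 9 libraries. Phyla and families together were 4 in males and 2 in females: 5 and 4 by DESeq2, 0 and 0 with PAE 11 to 19, 11 and 4 with PAE 20 to 29, and 0 and 1 without the 9 libraries. The 2 lists that changed in males became 0 on ranks, with controls 1 to 10, with PAE 11 to 19 and without the 9 libraries, and 4 with PAE 20 to 29, and in females the count stayed 0 under every alternative run. The cause was not tested.

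In males R2 of Bray-Curtis distances was 10.2% (exact permutation p = 0.139) with PAE 11 to 19 and 8.94% (0.166) without the 9 libraries. The Shannon difference was -0.12 (permutation p = 0.220) on genera, -0.34 with controls 30 to 37, 0.00896 with PAE 11 to 19 and 0.0175 without the 9 libraries. The difference in observed ASVs was -150.2, -59.8 and -49.2, and that in the log2 phylum ratio -0.58, -0.32 and -0.23, with controls 30 to 37, with PAE 11 to 19 and without the 9 libraries. In females R2 passed at 18.3% with controls 30 to 37 (n = 2) and 18.7% with PAE 20 to 29 (n = 4). Differences that did not pass under either setting changed sign in females: Shannon -0.0616 with PAE 20 to 29, observed ASVs 19.5 with controls 1 to 10 and 26.8 with PAE 11 to 19, and the log2 phylum ratio -0.0651 with controls 30 to 37 and -0.34 with PAE 20 to 29. The Shannon interaction was -0.28 with PAE 11 to 19 and -0.12 without the 9 libraries but passed at -0.73 with PAE 20 to 29. The ratio interaction was -0.59 with PAE 20 to 29 and -0.49 without the 9 libraries but passed at -0.80 with PAE 11 to 19. Leaving out 1 library gave R2 of 13.4% to 17.8% and 7.78% to 11.2% in males and females, Shannon differences of -0.54 to -0.40 and 0.05 to 0.22, and observed ASV differences of -205.9 to -166.9 and -37.0 to 21.8. All 21 male fits passed for these 3 measures and none of the 16 female fits did. The cause was not tested.

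The named genera gave 4100 values over 97 genus comparisons: 3729 kept direction and side of the threshold, 222 passed under neither setting with another sign, 91 became weaker, 52 stronger and 6 reversed. The log2 fold change of Hungatella in males became -5.50 with PAE 11 to 19 and -1.68 without the 9 libraries, and that of [Clostridium]_innocuum_group -2.12 and -0.91. That of Bifidobacterium in males, 1.13 as reported, was -4.79 by DESeq2 (adjusted p = 0.00463) and ranged from -5.94 without PAE male 25 (edgeR adjusted p = 0.0374) to 2.23 on leaving out other libraries. The values -4.79 and -5.94 passed as lower in PAE males, while the reported one did not pass. The cause was not tested. Flavonifractor, Clostridioides and Robinsoniella had no reads in the males of these 2 fits and gave no value there. Depth limits the rare genera most: with no read in control males, shares under 3 reads over the group were not detectable.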

Other observations

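The comparison of libraries with neighbouring numbers in this part was chosen only after the values were seen, as were the genera named. Helicobacter, a mucus-dwelling genus, held 2.01% to 7.88% of reads in controls 1 to 10, 1.77% to 10.1% in PAE libraries 11 to 19 and 1.40% to 7.05% in PAE libraries 20 to 29, but 0.00414% to 2.91% (median 0.195%) in controls 30 to 37. Ureaplasma, a wall-less mucosal genus, had 3385 reads in 4 of the 8 controls numbered 30 to 37 and 0 in the other 29 libraries. Candidatus_Saccharimonas had reads in controls 34 to 37 alone (1349 reads, up to 0.0873%). Enterococcus held 0.0309% to 0.134% in controls 1 to 10 and 0.0233% to 0.251% in PAE libraries 20 to 29, but at most 0.00239% in 11 to 19 and 0.00105% in 30 to 37. Clostridioides had reads in 6 of 10 libraries numbered 20 to 29 (up to 0.505%), in 1 of 10 numbered 1 to 10 (12 reads) and in 0 of the others.

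Control males also differed among themselves. Those numbered 1 to 10 and 30 to 37 were separated by a mean Bray-Curtis distance of 0.766 (R2 30.1%, exact permutation p = 0.00216), with 9 genera and 127 ASVs called between them. In control females edgeR called 0 genera (15 at an unadjusted p under 0.05) and 0 ASVs (116) between 30 to 37 (n = 2) and 1 to 10 (n = 5). Control males 1 to 10 and PAE males 16 to 19 were separated by 0.487 (R2 20.6%, exact permutation p = 0.0397). The other distances between the exposures were larger: 0.724 between control males 1 to 10 and PAE males 20 to 25 (R2 49.1%, exact permutation p = 0.00433), 0.751 between control males 30 to 37 and PAE males 16 to 19 (27.05%, 0.0333) and 0.868 between control males 30 to 37 and PAE males 20 to 25 (39.2%, 0.00216). PAE males 16 to 19 and 20 to 25 were separated by 0.737 (R2 49.1%, exact permutation p = 0.00476). Control females 3 and 10 shared high Blautia (6.67% and 5.14%), high Lachnoclostridium (8.06% and 11.01%) and low Lachnospiraceae_NK4A136_group (0.511% and 1.07%).

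Libraries with neighbouring label numbers had similar profiles. Within groups, pairs 1 number apart had a Bray-Curtis distance of 0.463 ± 0.178 (26 pairs) and other pairs 0.681 ± 0.156 (131 pairs; permutation p = 0.0001, the smallest these permutations can give). A cage that holds one sex of one exposure only is argued against as the whole cause, since pairs of one exposure and different sex that were 1 apart were also closer than other such pairs (0.537 ± 0.172 over 8 pairs and 0.668 ± 0.165 over 159, permutation p = 0.0122). A litter that holds both sexes and an order of handling, sequencing or birth within an exposure stay open. Only 2 pairs 1 number apart hold both exposures, too few to test an order that runs across the exposures. No biological explanation was tested for this pattern.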
